A study of Mus musculus with 6 samples.

How the data were processed

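The series holds 6 single-colour Illumina Mouse-6 BeadChip arrays of mouse retina, 3 of normal retinae and 3 of retinae after optic nerve crush with intravitreal PDGF-CC. Per the labels' protocols, RNA was extracted with TRIzol and purified on RNeasy columns, copied to cDNA with an oligo-dT primer, and transcribed to biotin-labelled cRNA. BeadStudio version 1 is named in the submitters' processing notes. The labels speak of 3 biological repeats and name a 2-tailed Student's t-test.

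The values the authors deposited are in the unit of a score: on each array the mean over the probes with a value lies within 0.01 of 0 and the SD within 0.01 of 1, so each value is a z-score of a probe's signal within its array. This was read from the values, and the steps before it, the log base included, are not given in the sources used here. A difference of 1 therefore means 1 SD of all probes of an array, and no fold change can be given. Such scaling removes differences in overall level and spread between arrays. It does not remove differences in shape: the skewness was 1.11 to 1.24 in control and 1.31 to 1.50 in the crush and PDGF-CC group. The design fixed before the data were examined assumed a log2 or linear scale, and the deposited table was kept as already normalized. A probe-level detection p was not used here, so signal over background is unknown.

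Of 46628 rows of the table, 16814 (36.1%) had a value, on all 6 arrays. There was no gene annotation table for the probes. Probe identifiers that hold a number after leading zeros were read as NCBI gene numbers and matched to the gene table of the mouse assembly GRCm38.p6, used for names only. This reading was checked in several ways. Of 11857 such identifiers 82.6% were found among the gene numbers, against at most 46.2% over 100 shifted numberings. Of 343 probes so named as olfactory receptors 1.17% had a value, against 49.0% of the others. For 12 pairs of probes named both in the identifier itself and by number, Pearson's r of mean z-scores across probes was 0.778. For 439 genes with several probes named by number it was 0.25, above the highest of 1000 shufflings (0.152), so names are right more often than chance but single names carry a doubt. Names read from cDNA clone numbers did not follow the other probes of the same gene (r = 0.006) and were not used. In all 4657 probes of 4156 genes had a name, mitochondrial transcripts and 18S ribosomal RNA among them, and 12157 probes with a value had none.

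Control, spike-in and viral rows and the 3 probes for 18S ribosomal RNA, 18 rows in all, were left out of the tests. Probes whose mean over the 6 arrays was at or above the median of all were tested, 8398 probes, of which those named stood for 2527 genes. The groups were compared with limma (lmFit and eBayes with default prior, group as the only term) and Benjamini-Hochberg adjustment over all probes tested, with a threshold of 0.05. A gene was represented by its probe with the highest mean over all arrays. Of 173 genes with several tested probes 28 had a changed probe, of which 9 changed only on a dimmer probe, and 0 had probes changed in opposite directions. Gene lists were tested with camera (preset inter-gene correlation 0.01, lists of at least 5 measured members, Benjamini-Hochberg over 13 lists), with the estimated correlation and fry as alternatives. Everything was computed with R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and the figures were drawn with matplotlib 3.10.9.

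The rule for named genes was fixed before the data were examined. It takes the 12 genes with the largest positive and the 12 with the largest negative difference among those past the threshold with no overlap between groups, up to 4 members with the smallest p in each list called by camera and up to 2 in each other list, and a fixed set of 21 genes. Of the 21 genes 4 had a value and 1 lay above the dim-probe filter. Some genes of that set are not reported here.

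The scripts were tested on simulated data made from the real means and within-group spreads of these 8398 probes, with 200 changed. Over 20 runs of this comparison 30.8% of the changes of 0.5 SD and 87.6% of the changes of 1 SD were recovered, and 4.21% of the calls were false. A list shifted by 0.3 SD was called by camera in 20 of 20 runs, with 0 lists called where none was shifted. That simulation drew genes independently, which real arrays are not.

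The alternatives fixed beforehand were quantile normalization, median centring, a floor at the 25th percentile, no dim-probe filter or a stricter one, a variance trend with robust fitting, the methods' t-test, the replicate number as a block, array weights, another choice of probe, leaving out each array in turn, and a threshold of 0.1. Fits with the title suffix as a batch term and with crush and PDGF-CC replicate 3 alone were added after seeing the data. Since the suffix occurs only on treated replicates 1 and 2, both estimate replicate 3 minus the controls and differ only in which arrays give the residual spread.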

Results

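Total RNA of mouse retina was measured on Illumina Mouse-6 Expression BeadChips, arrays on which biotin-labelled RNA binds probes carried by beads. The 6 arrays came from 8-week-old female mice labelled as PDGF-C deficient on the C57BL/6 background. In 3 of them the retinae were normal (control). In the other 3 the optic nerve, which carries the axons of the retinal ganglion cells to the brain, had been crushed, and active human PDGF-CC, a secreted growth factor, had been injected into the vitreous. Each injection was 1 µl at 0.5 µg/µl, given once a week for 2 weeks, and retinae were taken 7 days after the injury. The title of the series concerns the survival of neurons and GSK3b phosphorylation, and the comparison asks which transcripts differ between treated injured retinae and normal ones. No array of this series had the crush or an injection alone, so the injury, the injection and the protein were compared together. All 6 carry the same strain label, and the sample descriptions mention littermates without giving each mouse's genotype, so a difference in genotype between the groups was not checked. The deposited values were z-scores within each array, and every difference below is in units of an array's standard deviation (SD), not a fold change. The number of arrays, 3 per group, limits the precision.

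The control retinae resembled each other more than the treated ones did. Pearson's r between arrays, across 16796 probes, was 0.985 to 0.988 within control, 0.949 to 0.980 within the crush and PDGF-CC group, and 0.942 to 0.965 between groups. The mean r within groups exceeded that between groups by 0.0195. Crush and PDGF-CC replicate 3 did not follow that order: its r was 0.965 and 0.961 with control replicates 1 and 2, above the 0.954 and 0.949 with treated replicates 1 and 2, and 0.942 with control replicate 3. The first principal component held 45.4% of the variance of the probes tested and separated the groups. The second held 32.6% and set crush and PDGF-CC replicate 3 apart, with a score of 21.7 against -9.38 and -9.24 for replicates 1 and 2. Probes for 18S ribosomal RNA, the RNA of the small ribosomal subunit, followed the same division within the treated group. Their mean z-score was 4.24 and 4.55 in crush and PDGF-CC replicates 1 and 2 but 0.37 in replicate 3, beside 0.39, 0.61 and 0.16 in the controls. The titles of replicates 1 and 2 end in the letter A and that of replicate 3 does not.

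**Figure D1:**
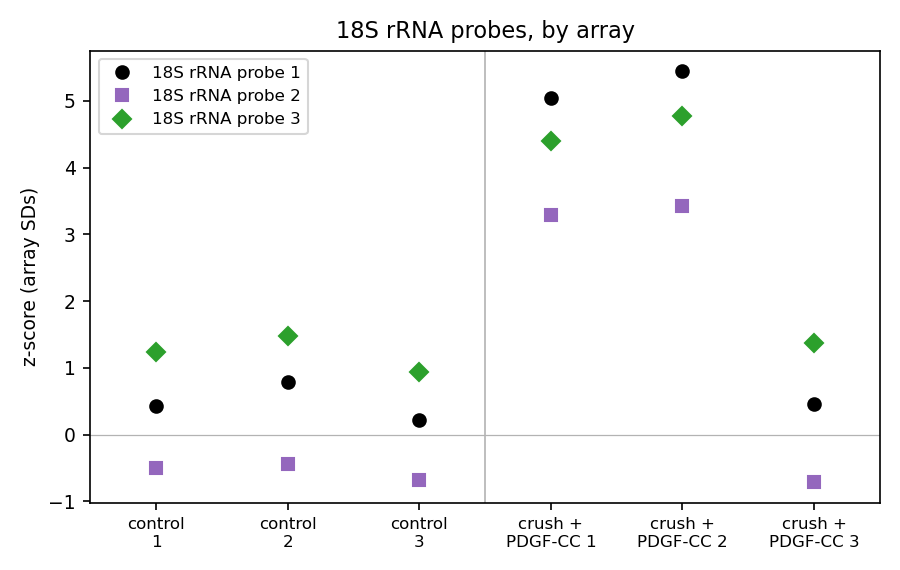
The 3 probes for 18S ribosomal RNA are plotted for each of the 6 arrays, with the z-score in array SDs on the vertical axis and 1 symbol per probe. Crush and PDGF-CC replicates 1 and 2 lie between 3.29 and 5.44, whereas crush and PDGF-CC replicate 3 and the controls lie between -0.71 and 1.48.

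Among the genes tested, the largest increase after crush and PDGF-CC was that of Xist, the long non-coding RNA that silences an X chromosome in female cells. Its z-score was 0.22 ± 0.23 (SD, n = 3) in control and 1.61 ± 0.96 (SD, n = 3) after treatment, a difference of 1.39 ± 0.33 (SE; limma adjusted p = 0.0277). The sodium bicarbonate cotransporter gene Slc4a7 rose by 1.23 ± 0.23 (SE) and Map1b, which encodes a microtubule-associated protein of growing axons, rose by 1.14 ± 0.22 (SE), both with an adjusted p of 0.0152. The imprinted zinc finger gene Peg3 rose by 1.04, the stress granule protein gene G3bp2 by 0.95 and Pitpnm3 by 0.91. Kdm2a, a histone demethylase gene, rose by 0.89, the cell junction gene Afdn by 0.84 and the ubiquitin ligase gene Pja2 by 0.82. By the rule for naming them, these 9 genes were higher in all 3 treated arrays than in any control array. For Xist, Slc4a7, Map1b, Peg3, G3bp2, Pitpnm3 and Pja2 the treated replicate 3 lay closest to the controls. Xist was 2.38 and 1.91 in replicates 1 and 2 and 0.54 in replicate 3, beside at most 0.48 in control. With the title suffix as a batch term the group difference is that of replicate 3 minus the controls, a treated arm of 1 array whose spread is borrowed from the other arrays. In that fit Xist (adjusted p = 0.239), Peg3 (0.0682), Pitpnm3 (0.0567) and Pja2 (0.063) missed the threshold. With the dim-probe filter lifted, Xist, Peg3 and Kdm2a missed it (adjusted p = 0.0821, 0.0532 and 0.0593). More probes are adjusted for in that fit, but the SE and unadjusted p of these 3 genes rose as well. For Xist the unadjusted limma p went from 0.00098 to 0.0064.

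A second set of rises belonged to the brightest probes on the array. The mitochondrially encoded transcripts mt-CytB and mt-ND4, which encode subunits of respiratory complexes III and I, rose by 0.89 ± 0.16 and 0.83 ± 0.16 (SE), and Sag, the rod photoreceptor arrestin, rose by 0.86 ± 0.17 (SE). Their limma adjusted p were 0.0147, 0.0152 and 0.0161. After quantile normalization, which gives every array the same distribution, the differences were 0.06 for mt-CytB, -0.03 for mt-ND4 and 0.13 for Sag, and none of these 3 genes passed the test (adjusted p = 0.787, 0.910 and 0.512). Probes near the top of every array receive close to the same values on each after this step, whatever the cause of a difference. It therefore cannot separate a rise of these genes from an effect of the scaling.

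Decreases were more even across the treated arrays. Faah, the gene of the enzyme that breaks down the endocannabinoid anandamide, had the largest decrease, from 1.20 ± 0.14 (SD, n = 3) to 0.34 ± 0.30 (SD, n = 3), a difference of -0.86 ± 0.15 (SE; limma adjusted p = 0.0141). Of its 2 probes tested, 1 passed. Prpsap2, which encodes a partner of phosphoribosyl pyrophosphate synthetase, fell by 0.76, and the ubiquitin ligase gene Traf7 fell by 0.75. Cd59b, an inhibitor of the complement membrane attack complex, fell by 0.75, as did the LIM domain gene Crip2. Lysmd1 also fell by 0.75. Wasf1, a regulator of actin branching, fell by 0.71 ± 0.11 (SE; adjusted p = 0.0106), from 1.55 ± 0.08 to 0.83 ± 0.04 (SD, n = 3 each). The splicing factor gene Hnrnpa1 fell by 0.71, the transcriptional repressor gene Brms1 by 0.70 and the alpha-tubulin gene Tuba1a by 0.70. Zpr1 also fell by 0.70, and Chmp5, a component of the ESCRT-III membrane remodelling complex, fell by 0.69. By the same naming rule, all 12 of these genes were lower in every treated array than in any control array. They also passed the test after quantile normalization. For Faah, Prpsap2, Traf7, Crip2, Wasf1, Brms1, Tuba1a and Zpr1 the treated replicate 3 lay farthest from the controls, and for Cd59b, Hnrnpa1 and Chmp5 closest. Faah was 0.57 and 0.46 in replicates 1 and 2 and -0.01 in replicate 3. With the filter lifted Traf7 and Tuba1a missed the threshold (adjusted p = 0.0526 and 0.0547).

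**Figure D2:**
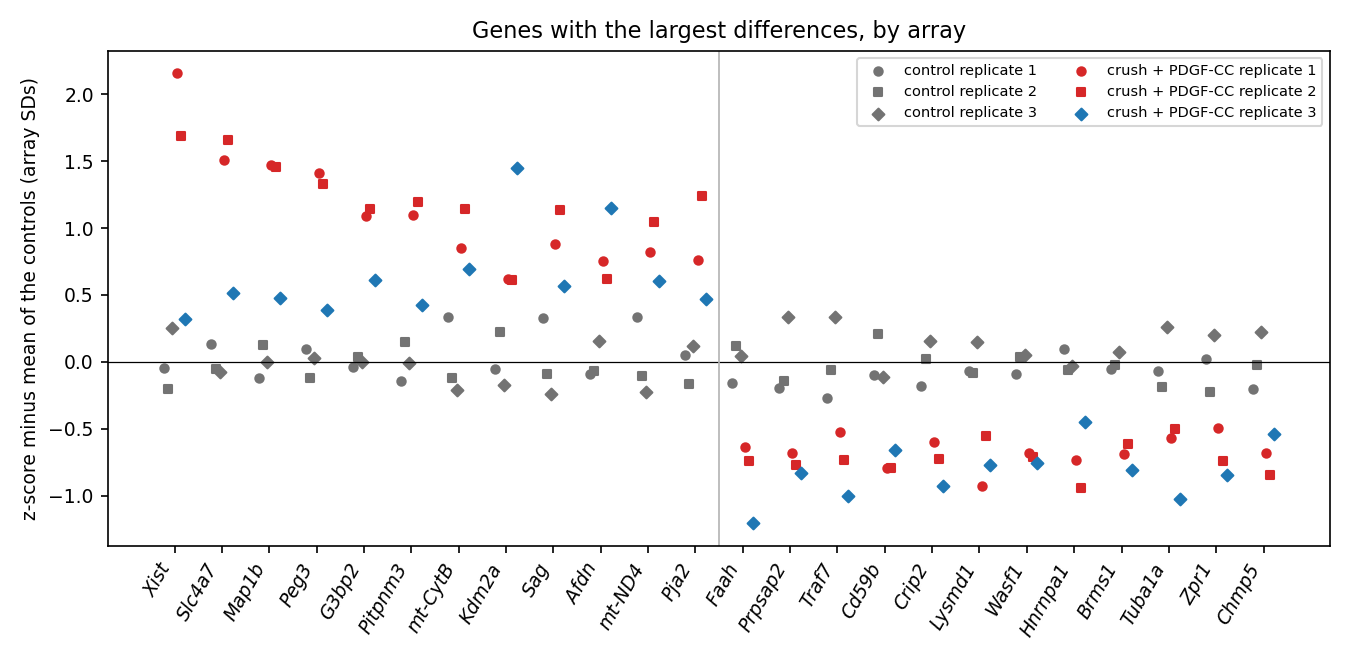
The 12 genes with the largest increases and the 12 with the largest decreases are plotted along the horizontal axis, with each array's z-score minus the mean of the controls, in array SDs, on the vertical axis. Grey symbols are the 3 control arrays, red symbols crush and PDGF-CC replicates 1 and 2, and blue diamonds replicate 3. Every treated array lies above every control array for the first 12 genes and below for the others, as the naming rule required. Replicate 3 lies 0.32 above the control mean for Xist.

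Across 2527 named genes, 158 changed, 58 of them higher and 100 lower after crush and PDGF-CC (limma with Benjamini-Hochberg adjustment, threshold 0.05). The share higher was 36.7% (95% exact binomial interval 29.2 to 44.7%, which treats genes as independent). It was 42.4% after quantile normalization and 42% with median centring. The median difference of all probes tested was -0.058 as deposited and -0.027 after quantile normalization. An effect of the scaling on this share was not excluded. Over all 8398 probes tested, most of them without a gene name here, 554 changed, 296 higher and 258 lower. After quantile normalization 288 probes were higher and 154 lower. At an unadjusted p under 0.05, 663 genes differed. Of the probes tested, 32.7% had no overlap between the groups, where chance gives 10% for 3 arrays against 3. The methods' t-test, the test that the series states, gave 509 genes at its unadjusted threshold and 0 after Benjamini-Hochberg adjustment. The limma count was 32, 0 and 0 without control replicate 1, 2 or 3, with 458 and 437 genes at an unadjusted p under 0.05 for the last pair, and 81, 74 and 584 without crush and PDGF-CC replicate 1, 2 or 3. Replicate 3 minus the controls, a treated arm of 1 array, gave 446 genes when the spread was taken from the other 5 arrays (the fit with the title suffix) and 484 when it was taken from the controls. Of these 122 and 127 were among the 158. Both are the same contrast, and neither measures how treated retinae vary.

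Of 34 gene lists fixed before the data were examined, 13 had at least 5 members above the dim-probe filter and were tested. Of these, 1 was called, that of glycolysis and the hypoxia response, and its call depended on the test and the normalization. Of 14 measured members 10 were higher and 4 lower in the mean, 5 rose, 0 fell and 9 did not pass, and 6 changed when adjusted over the list alone. Gapdh, the enzyme that oxidises glyceraldehyde 3-phosphate, rose by 0.79 ± 0.15 (SE; limma adjusted p = 0.0152) on its brighter probe, and 1 of its 2 probes passed. Hk1, the hexokinase that starts glycolysis, rose by 0.66 ± 0.13 (SE; adjusted p = 0.0152). The pyruvate kinase gene Pkm rose by 0.60 and the lactate dehydrogenase gene Ldha by 0.53. The fifth gene was the enolase gene Eno1, with a rise of 0.57, named here after its value was seen. The members that changed are glycolytic enzymes. The median difference of the list was 0.28 (camera adjusted p = 2.14e-05, preset correlation), while the adjusted p = 0.566 with an estimated correlation and 0.116 with fry. By array the median was 0.385, 0.206 and 0.166 above the controls in replicates 1, 2 and 3, and without replicate 1 it was 0.157 with the call kept. After quantile normalization the median was 0.18 and the list was not called (adjusted p = 0.101), and of the 4 enzymes named by rule Hk1 alone passed, with a difference of 0.68, against 0.28 for Gapdh, 0.20 for Pkm and 0.21 for Ldha. Eno1 kept 0.51 and missed the threshold (adjusted p = 0.0922). No other list was called in the planned comparison, with either correlation.

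**Figure D3:**
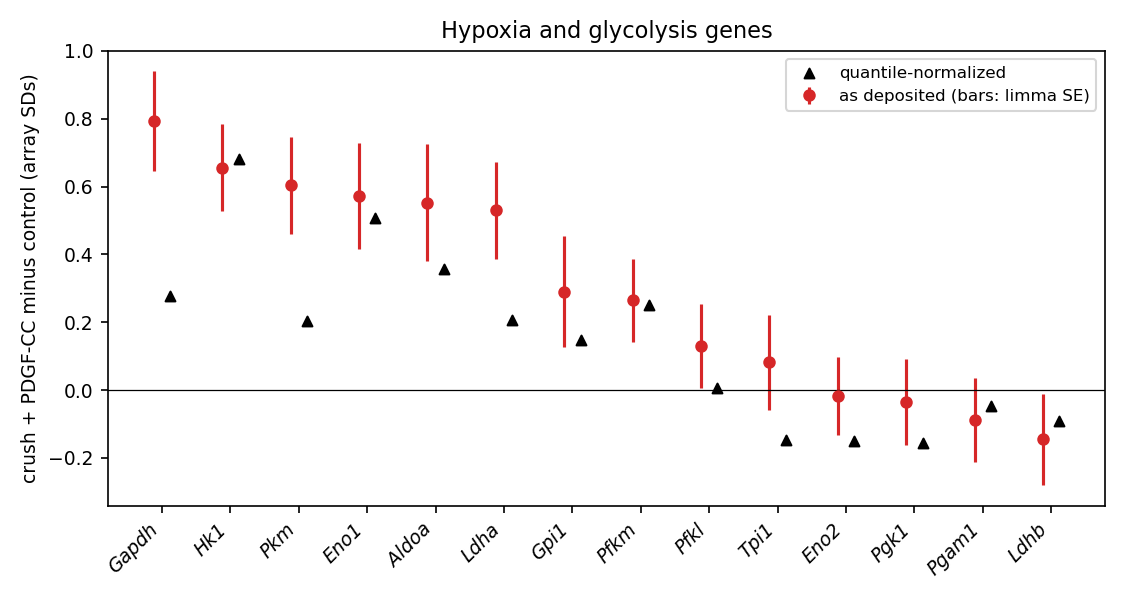
The 14 measured genes of the hypoxia and glycolysis list are plotted along the horizontal axis, with the difference between crush and PDGF-CC and control in array SDs on the vertical axis. Red points are the deposited values with limma's SE as bars, and black triangles the values after quantile normalization. Gapdh moves from 0.79 to 0.28 between them and Hk1 from 0.66 to 0.68.

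Markers of retinal cell types moved in single genes. Calb2, the gene of the calcium-binding protein calretinin, fell by 0.45 ± 0.12 (SE, limma adjusted p = 0.0448). It was listed with amacrine and horizontal cell markers, and which retinal cells carried its fall was not measured. Prox1, a transcription factor of horizontal and AII amacrine cells, differed by -0.56 (adjusted p = 0.0683). Of 6 amacrine and horizontal cell markers 1 fell, 0 rose and 5 did not pass, and 3 changed when adjusted over the list alone. The list had a median of -0.28 (camera adjusted p = 0.252), with 5 of the 6 lower. Replicate 3 minus the controls, 1 treated array, called it downward at a median of -0.43 (adjusted p = 0.04996 and 0.0496 in the 2 fits), with the preset correlation of 0.01. With the estimated one, 0.094, the adjusted p over the 6 arrays was 0.663. Among Müller glia markers, Apoe, which encodes the main lipid carrier of the retina and brain, rose by 0.78 ± 0.14 (SE; adjusted p = 0.0147), and the water channel gene Aqp4 differed by 0.35 (adjusted p = 0.114). Both changed when adjusted over that list of 2 alone. With the filter lifted 5 were measured, 1 rose and 3 changed when adjusted over the list alone, with a median of -0.04. The third was Spon1, at -0.40 (adjusted p = 0.145 over all genes), while Sox2 and Cp differed by -0.05 and -0.04. Of 4 rod genes 1 rose, the Sag described above. Nrl, the transcription factor of rod fate, differed by 0.49 (adjusted p = 0.131), and by -0.05 for replicate 3 minus the controls. After quantile normalization it differed by 0.05 (adjusted p = 0.878). Nrl is also among the brightest probes, so that step cannot separate a rise from the scaling. Adjusted over the rod list alone, 1 gene changed. The cone genes Arr3 and Gnb3 differed by -0.43 and -0.04 and neither passed, although 1 of the 2 changed when adjusted over the list alone. For replicate 3 minus the controls Arr3 differed by -0.002. Otx2, listed with bipolar cell markers, differed by 0.22 (adjusted p = 0.279), and which retinal cells carried its signal was not measured. The retinal ganglion cell markers above the filter, Gap43 and Jam2, differed by -0.15 and -0.08 (adjusted p = 0.445 and 0.757), and with the filter lifted 0 of 8 measured markers passed and 0 changed when adjusted over the list alone. Of 13 synaptic genes 1 passed, the adhesion receptor gene Nrxn3, which rose by 0.55 (adjusted p = 0.0235). Syt1, the calcium sensor of vesicle release, differed by 0.48 (adjusted p = 0.0709). For replicate 3 minus the controls Nrxn3 differed by 0.42 and Syt1 by 0.20. Adjusted over the synaptic list alone, 2 genes changed.

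The lists of reactive gliosis and of interferon and antigen presentation genes were not called in the planned test, and the other inflammation lists had too few members for it. Of 6 reactive gliosis genes Cntf, the ciliary neurotrophic factor gene, fell by 0.45 ± 0.12 (SE; limma adjusted p = 0.0402), and 5 did not pass. After quantile normalization Cntf missed the threshold (adjusted p = 0.0644). The metallothionein gene Mt1 differed by 0.49 (adjusted p = 0.0682), and by 0.12 for replicate 3 minus the controls. After quantile normalization it differed by 0.15 (adjusted p = 0.500). Mt1 is among the brightest probes, so that step cannot separate a rise from the scaling. The 6 members had a median difference of 0.21 (camera adjusted p = 0.320), and 2 changed when adjusted over the list alone. The list was called upward with array weights (median 0.346, adjusted p = 0.00917), with the preset correlation of 0.01. The correlation estimated for this list was 0.470, with an adjusted p of 0.704 in the unweighted comparison. Without crush and PDGF-CC replicate 1 the median was -0.0016 (adjusted p = 0.991), and for replicate 3 minus the controls it was -0.28. The 4 microglia and macrophage genes above the filter did not pass, among them Spp1 at -0.20 and the complement gene C1qb at -0.13. With the filter lifted 11 were measured, 0 passed and the list was not called (camera adjusted p = 0.933). Of 7 interferon and antigen presentation genes 0 passed, and 1 changed when adjusted over the list alone. B2m, the light chain of MHC class I, differed by -0.59 (adjusted p = 0.0517), but by -0.17 for replicate 3 minus the controls, and Ifit3 by -0.41 (adjusted p = 0.113). The list of lymphocyte and neutrophil genes had 0 members with a value.

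The genes that the series' title points to were measured only in part. Of the 8 PDGF and GSK3 genes, Pdgfa and Pdgfd had a value, both below the dim-probe filter. Pdgfa was -0.99 ± 0.07 in control and -0.76 ± 0.17 after treatment (SD, n = 3 each), a difference of 0.22 ± 0.10 (SE; limma adjusted p = 0.208 with the filter lifted). Pdgfd differed by -0.10 ± 0.09 (SE; adjusted p = 0.535), so 0 of these genes passed, and 0 had an unadjusted p under 0.05. Pdgfc, Pdgfb, Pdgfra, Pdgfrb, Gsk3a and Gsk3b were not analysed here. The only other member of the PDGF list above the filter, the co-receptor gene Nrp1, differed by -0.09 (adjusted p = 0.682). In the list of GSK3, PI3K, AKT and Wnt pathway genes 0 of 5 passed over all genes tested and 2 changed when adjusted over the list alone, at a median of 0.15 (camera adjusted p = 0.117). They included Pik3r1, a regulatory subunit of PI3-kinase, at 0.47 (adjusted p = 0.0644) and the tau gene Mapt at 0.39 (adjusted p = 0.0789). For replicate 3 minus the controls Pik3r1 differed by 0.16 and Mapt by 0.44, and the list's median was 0.0002.

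Apoptosis genes did not pass the test. Bcl2, the founding anti-apoptotic gene, was 0.10 ± 0.12 in control and -0.24 ± 0.11 after treatment (SD, n = 3 each), a difference of -0.34 ± 0.12 (SE; limma adjusted p = 0.0976). The inhibitor of apoptosis gene Birc2 differed by -0.22 (adjusted p = 0.309), and 0 of 6 anti-apoptotic genes passed (camera adjusted p = 0.795). That list's median of -0.07 lay below 0 while camera, which compares it with the other genes, put it upward. Among pro-apoptotic genes Casp2 differed by -0.34 (adjusted p = 0.125) and the cytochrome c gene Cycs by -0.23 (adjusted p = 0.283), and 0 of 4 passed. With the filter lifted 11 pro-apoptotic genes were measured, 0 passed, and 2 changed when adjusted over the list alone. Gfap, Pou4f1, Pou4f2, Sncg, Nefl, Thy1, Opn1sw, Aif1, Atf3 and Bax were not analysed here.

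The larger housekeeping lists held few changes. Of 62 cytosolic ribosomal protein genes 2 rose and 2 fell, 7 changed when adjusted over the list alone, and the median difference was 0.01 (camera adjusted p = 0.117). Camera called this list upward without control replicate 2 (adjusted p = 0.00146), without crush and PDGF-CC replicate 2 (0.0207) and for replicate 3 minus the controls (0.0457 and 0.0476), at medians of at most 0.08. After quantile normalization it lay downward and was not called (0.494). Those calls use the preset correlation of 0.01, whereas the correlation estimated for this list was 0.286, with an adjusted p of 0.704 over the 6 arrays. Rpl41 rose by 0.53 and Rpl23a fell by 0.58 (adjusted p = 0.0300 and 0.0230). After quantile normalization Rpl41 differed by 0.13 and no longer passed, but it is among the brightest probes, where that step cannot separate a rise from the scaling. Of 36 nuclear-encoded oxidative phosphorylation genes 1 fell, the complex I gene Ndufa9, by 0.47 (adjusted p = 0.0439), which missed the threshold after quantile normalization (0.0655). Uqcrb of complex III differed by -0.58 (adjusted p = 0.0591), but by -0.16 for replicate 3 minus the controls. The list's median was -0.14 (camera adjusted p = 0.558). It was -0.06 without control replicate 2 and -0.07 without crush and PDGF-CC replicate 2, where camera put the list upward without calling it. Of 12 proteasome genes 0 passed, also when adjusted over the list alone, with Psmd1 at 0.37 and Psmb5 at -0.38. For replicate 3 minus the controls Psmd1 differed by 0.53 and Psmb5 by -0.11. Of 9 antioxidant genes 0 passed, with Prdx2 and Gstm1 both at -0.15. Of 6 axon injury and regeneration genes 0 passed, with Klf7 at 0.31 and the adhesion molecule gene Ncam1 at 0.34. For replicate 3 minus the controls Klf7 differed by 0.30 and Ncam1 by 0.07. That list's median was 0.13 over all arrays and 0.009 for replicate 3 minus the controls. Of 6 cholesterol synthesis genes 0 passed and 1 changed when adjusted over the list alone. Fdps differed by -0.42 (adjusted p = 0.0517), and camera's adjusted p was 0.719 beside 0.0254 with fry, which tests the list by itself and not against other genes.

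The lists not yet described had fewer than 5 members above the filter and were not tested as groups in the planned comparison. With the filter lifted the extracellular matrix, neurotrophic and cell cycle lists could be tested, and none was called (camera adjusted p = 0.664, 0.664 and 0.950). None of their members passed over all genes tested. Adjusted over the list alone, 1 of 3 extracellular matrix genes and 1 of 3 neurotrophic genes above the filter changed. With the filter lifted the counts were 0 of 6 and 2 of 5, and 1 of 7 cell cycle genes changed. Timp2 and Timp3, of the extracellular matrix list, differed by -0.41 and 0.28, and Serpinf1 and Gfra1, of the neurotrophic list, by -0.41 and -0.19. For replicate 3 minus the controls Timp2 and Timp3 differed by -0.07 and 0.16, and Serpinf1 and Gfra1 by -0.64 and -0.18. Pcna and Cdkn1a of the cell cycle list differed by -0.26 and 0.01, Xbp1 and Hspa5 of the unfolded protein response by -0.11 and -0.07, and the histone genes H3f3b and H3f3a by 0.06 and -0.02. Crygb and Crygc of the lens list differed by -0.59 and -0.22, the haemoglobin gene Hba-a1 by 0.19 and Enpp2 of the pigment epithelium list by 0.06. The lists of immediate early, vascular endothelial and pericyte genes had 4, 2 and 1 members with a value, all below the filter, and 0 of them passed with the filter lifted. The skeletal muscle list had 0 members with a value.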

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

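The tests of this part were chosen after the values were seen. Probes for 18S ribosomal RNA, which took part in no comparison, gave a mean z-score of 4.24 in crush and PDGF-CC replicate 1 and 4.55 in replicate 2, above the highest control at 0.61. Replicate 3 of the same group was at 0.37, within the control range. An oligo-dT primer should copy little of this RNA, which has no poly(A) tail. Replicate 3 differed from replicates 1 and 2 together on 1022 of 8398 probes (limma, Benjamini-Hochberg), whereas replicate 1 differed from the other pair on 14 and replicate 2 on 0. Each of these counts has 1 array on one side. When replicate 1 or 2 is the single array, the pair holds replicate 3, which widens the residual spread and can lower the count. The counts are thus not on an equal footing, and they describe again the division already seen in the similarity of the arrays. A preparation batch shared by replicates 1 and 2, whose titles end in A, therefore stays open. A difference between the mice or their dissection would divide the arrays in the same manner and was not tested. An effect of the crush or the protein on 18S signal stays open too, because the value of 0.37 against it comes from 1 array.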

How the results depend on the processing

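The fits with the title suffix were chosen after seeing the data, as was quantile normalization for the similarity of arrays. The count of 158 genes stayed within 1.5 times under quantile normalization (118), median centring, the 25th percentile floor, no dim-probe filter, a variance trend, the replicate block (126) and the other choice of probe. It was 105 with the stricter filter (fewer genes tested), 748 with array weights, 406 at a threshold of 0.1, and 509 and 0 with the methods' t-test before and after adjustment. It was 446 and 484 in the suffix fits, which both compare crush and PDGF-CC replicate 3 alone with the controls. Leaving out 1 array gave 0 to 584 genes, with fewer samples in each such fit. The cause of the other changes was not tested. The share of genes higher was 36.7%, and 28.7% with the t-test, 27.8% and 28.5% with the suffix fits, and 37.5 to 53.1% without 1 array. Quantile normalization kept 103 of the 158 genes and turned the sign of mt-ND4 to -0.025. Of the 24 genes named by size, 21 remained past the threshold under quantile normalization, 19 with no dim-probe filter, 14 without control replicate 1, and 0 without control replicate 2 or control replicate 3. The count of 1 list became 0 with quantile normalization and with the estimated correlation, 2 with array weights, 3 with either suffix fit, and 1 to 2 without 1 array. With fry the count of lists was also 1, but the list called was cholesterol synthesis (adjusted p = 0.0254) and not glycolysis (0.116). The PDGF and GSK3 count stayed at 0 after adjustment in each setting run. Pdgfa had an unadjusted limma p of 0.0369 with median centring and 0.0139 without crush and PDGF-CC replicate 2. The similarity of arrays moved from 0.0195 to 0.0179 under quantile normalization. The replicate numbers gave no sign of a pairing of the arrays: deviations of equal-numbered arrays from their group means correlated at -0.17, -0.29 and -0.39. Deviations of 3 arrays from their own mean depend on each other, so these values cannot exclude a pairing. The replicate block left 1 list called. A minimum of 1.5-fold could not be run, since z-scores give no folds. Signal over background is unknown, and lower brightness limits what the filter lets through.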

Other observations

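The tests on the glycolysis list in this part were chosen after the values were seen, and the counts over other splits of the arrays were planned. The genes of the next paragraphs were also chosen after their values were seen.

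Most mitochondrially encoded transcripts were bright, at 2.84 or above on every array, except for mt-ND4L, mt-ND6 and 1 of 2 probes of mt-ND5. Of the 11 tested genes 7 rose after crush and PDGF-CC (limma, Benjamini-Hochberg). Besides mt-CytB and mt-ND4, mt-COXIII rose by 0.74, mt-ATP6 by 0.72, mt-ND1 by 0.61, mt-ND2 by 0.60 and mt-COXI by 0.57. After quantile normalization 0 of the 11 genes passed in either direction, and the differences were 0.02 for mt-COXIII, 0.13 for mt-ATP6, -0.03 for mt-ND1, 0.33 for mt-ND2 and -0.11 for mt-COXI. As with mt-CytB and mt-ND4, this cannot separate a rise of the brightest transcripts from an effect of the scaling. The 2 probes of mt-ND4L went the other way. The brighter differed by -0.50 and did not pass (limma adjusted p = 0.0577), while the dimmer fell by 0.67 (adjusted p = 0.0476). After quantile normalization they differed by -0.52 and -0.62, and neither passed (adjusted p = 0.0625 and 0.0675). For replicate 3 minus the controls the differences were -0.17 and -0.13. mt-ND6, below the dim-probe filter, differed by -0.51 (unadjusted p = 0.0106, adjusted p = 0.0973 with the filter lifted).

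Genes of the lens and cornea varied between single arrays, with overlap between the groups. The lens gamma-crystallin gene Crygb was 2.75, 0.04 and -0.67 in crush and PDGF-CC replicates 1, 2 and 3, and 1.44, 0.69 and 1.77 in the controls. Crygd was 2.56, -0.41 and -0.68 in those treated arrays and 0.78, 0.13 and 1.08 in the controls. Krt12, a keratin gene of the corneal epithelium, was 1.03 in crush and PDGF-CC replicate 3 and at most -0.11 on any other array. Serpina3n, a gene of reactive astrocytes and Müller glia, was 0.06 in crush and PDGF-CC replicate 3 and 1.09 to 1.83 on the other arrays. The probe for the transcription factor gene Klf2, below the dim-probe filter, was at -4.34 and -4.59 in crush and PDGF-CC replicates 1 and 2. It was at -1.24 in replicate 3 and at -1.09 to -0.88 in the controls. The values of replicates 1 and 2 were the lowest of their arrays, whose 1st percentiles were -1.12 and -1.14.

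The higher median of the glycolysis list was weighed against 2 technical explanations. Scaling each array to unit spread may raise bright probes where the distribution has a longer bright tail, as it had on the treated arrays. Under quantile normalization the list's median went from 0.277 to 0.176 and its call ended, while Hk1, a dimmer gene, kept its difference, so scaling as part of the rise stays open. For a preparation batch of crush and PDGF-CC replicates 1 and 2, the value at hand is that of replicate 3: its list median lay 0.166 above the mean of the controls, beside 0.0902 for the highest control against the other controls, which is too small a gap from 1 array to exclude that explanation. For replicate 3 minus the controls, Gapdh differed by 0.78, Pkm by 0.70, Ldha by 0.70, Eno1 by 0.83 and Hk1 by 0.44. Pkm, Ldha and Eno1 were higher in replicate 3 than in replicates 1 and 2. As all of these values come from the same treated array, they cannot decide the question, and a batch stays open. An effect of the crush, the injection or PDGF-CC stays open, and these 3 cannot be separated in this design.

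The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 158 genes, the highest other split gave 0, and the real split was thus the 1 with a count as large. Every other split mixes the conditions, so any difference between the groups, of whatever cause, enters its residual spread. A count of 0 there is therefore no support for the real grouping. For gene lists the real split gave 1 and the highest other split 4, and 8 of the 10 splits gave at least as many as the real one. Of the 9 other splits 4 called the hypoxia and glycolysis list, but each of those splits leaves 2 arrays of one condition beside 1 of the other, and so keeps part of any treatment difference. These calls therefore do not separate the treatment from other structure among the arrays.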
